A study of Danio rerio with 4 samples.

How the data were processed

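RNA from embryonic brain of wild-type zebrafish (1 array) and of foggy mutants (3 arrays) was measured on the Affymetrix zebrafish genome array, in which each transcript is read by a set of short probes. Per the labels, the wild-type sample was taken at 36 h. The labels of the mutant samples give 36 without a unit, which was read as hours. The labels name the tissue as brain and do not say whether eyes, skull cartilage, blood or other head tissue came with it. The labels number the mutant samples 1 to 3 and do not say whether they came from separate clutches, dissections or RNA extractions.

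The authors deposited 1 table of probe set intensity values on a linear scale for the 4 arrays. The software that summarised the probes, its version, the background correction and the detection calls are not given in the sources used here. The deposited intensity values were already scaled between arrays, because the mean after trimming 2% of the values at each end was 150.03 in each of the 4 arrays. They were therefore used as deposited. Such scaling removes any change common to most transcripts, so each rise or fall below is relative to the other transcripts of its array. The rule for this, the tests, the 34 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Of the 4 columns, all were mapped to a sample by the labels, and no values were identical between any pair of arrays.

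The table held 15617 probe sets. The 115 control probe sets were left out of the tests. A pseudocount of 16.252 intensity units, the 20th percentile of all values, was added before taking log2. The 4651 probe sets whose mean log2 value lay under the 30th percentile were removed as dim, which left 10851. Every fold change below is on the log2(value + pseudocount) scale and understates the change of weakly expressed genes. Gene symbols came from the platform's public annotation, which is of an older date, and were updated through the gene number with the RefSeq gene table of assembly GRCz12tu, used for names only. Of the 15617 probe sets, 10802 had 1 symbol, 135 had several and 4680 had none here. The gene number was matched for 10718 of the 10802, and 1 symbol changed. Probe sets without a single symbol were tested and counted but are unnamed. The tested probe sets covered 6852 named genes.

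Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance in mean expression), mutant against wild type. P-values are two-sided and Benjamini-Hochberg adjusted over the 10851 probe sets, with 0.05 as the threshold. With 1 wild-type array the spread came from the 3 mutant arrays alone, with 2 residual degrees of freedom and 7.89 prior degrees of freedom, and the wild-type array was assumed to vary like the mutant arrays. A permutation of the 4 arrays cannot give a p below 0.25. A rule of size was therefore set beside the test, counting probe sets at which all 3 mutant arrays differed from the wild-type array by at least 1 on the log2 scale in the same direction. The p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

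The 34 gene lists were elongation factors, RNA polymerase II subunits, splicing, heat shock, p53 response and apoptosis, immediate early genes, unfolded protein and amino acid response, hypoxia response, catecholaminergic neurons, serotonergic neurons, neural progenitors, differentiated neurons, glia and oligodendrocytes, cell cycle and DNA replication, brain region transcription factors, lens, retina and photoreceptors, skeletal muscle, heart muscle, red blood cells, white blood cells, blood vessels, epidermis, pigment cells, cartilage and mesenchyme, yolk and liver, ribosomal proteins, proteasome, oxidative phosphorylation, translation factors, cholesterol and lipid synthesis, circadian and light response, Hedgehog, Wnt, Fgf and Bmp targets, and matrix and wound response. Lists defined by a pattern in the symbol left out kinases and binding proteins that share the prefix. Each gene was represented by its brightest probe set. Lists were tested with camera (limma) with the correlation between genes preset at 0.01, two-sided and adjusted over the 34 lists, and again with the correlation estimated from the data. The preset value is an assumption. The estimate rests on 2 residual degrees of freedom, so the second test has little power and a list not called there is left undecided. The median log2 difference of each list was also placed among 10000 random lists of the same size matched on mean expression. Another 4 lists (cortisol-induced genes, muscle regulators, muscle contractile genes, general transcription factors) were written after the first results were seen and are used only in the closing section. Their camera p-values were adjusted over these 4 lists alone.

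The rule for named genes took, from probe sets with 1 gene symbol, a higher group mean at or above the median of all probe sets and a difference of at least 1 (log2) in all 3 mutant arrays, the 12 largest rises and the 12 largest falls past the adjusted p, with 1 probe set per gene. It added supt5h, th, tph2, slc6a3 and slc18a2, and from each list the 4 measured members with the smallest p. Genes named outside this rule are marked as chosen after their values were seen.

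The fit was tested on simulated arrays of the 10851 probe sets, 200 of them changed, in 10 runs. It recovered 36.4% of changes of 0.5 on the log2 scale, 86.4% of changes of 1 and 99.8% of changes of 2, and 3.53% of its calls were false. These runs drew each variance from the spread that the fit itself had estimated, with a wild-type array that varied like the mutant arrays. They therefore show how the fit performs where its assumptions hold, and not its share of false calls in the real arrays. In 10 simulations without any change it made 0 calls when the wild-type array varied like the mutant arrays. When the wild-type SD was 2 times as large, it made a median of 496.5 calls, and a median of 25 probe sets met the rule of size. When the wild-type SD was 3 times as large, these numbers were 3119 and 173.5. No gene list was called in any of these runs, but the probe sets were simulated independently of one another. Genes of a real list can vary together, so these runs do not show how often camera calls lists of correlated genes.

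The alternatives were quantile normalization, median centring and cyclic loess, pseudocounts at the 5th and 40th percentiles, no filter and a filter at the 50th percentile, eBayes without the trend and robust eBayes, each mutant array left out in turn, an estimated correlation in camera, and the mean of a gene's probe sets. A fit in which the wild-type SD was taken as 2 times the mutant SD was added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.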

Results

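Gene expression was compared between the brain of wild-type zebrafish embryos and that of foggy mutant embryos at 36 h. The tissue is named as brain in the labels, which do not say whether eyes, cartilage, muscle or blood came with it. The foggy locus encodes Spt5 (supt5h), a factor that binds RNA polymerase II and both pauses it near promoters and helps it through elongation. The mutant was isolated for its altered dopamine and serotonin neurons. The data were 1 array of wild-type brain RNA and 3 arrays of mutant brain RNA, each with 15617 probe sets. Median signals were 65.4 in the wild-type array and 65.3, 65.4 and 66.0 in the mutant arrays.

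The transcript of the mutated gene was not lower in the mutant. The supt5h probe set read 210 in the wild-type array and 258, 245 and 254 in the mutant arrays. The log2 difference of +0.25 (SE 0.087) did not pass limma's test (adjusted p = 0.137), and it passed without mutant array 1 (adjusted p = 0.0447). Mutant arrays 2 and 3 were the most alike (SD of their log2 differences 0.158), so fits without mutant array 1 rest on a small spread and pass more probe sets. A pass gained there is weak evidence, here and below. A point mutation need not change the transcript level, so the supt5h probe set neither supports nor contradicts the labels. Some marker genes of the affected neurons were hard to read at this signal level. Both probe sets of th, which encodes tyrosine hydroxylase, and that of the dopamine transporter slc6a3 were dim in all 4 arrays (highest signals 3.99 and 8.06) and were not tested. The slc18a2 gene was not on a named probe set. The serotonin enzyme gene tph2 read 60.8 in the wild type and 35.3 ± 8.62 (SD, n = 3) in the mutants, a log2 difference of -0.59 (SE 0.203) that did not pass (adjusted p = 0.128) and passed without mutant array 1 (adjusted p = 0.00827).

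The named genes with the largest differences were lower in the mutant. Some genes of embryonic globins, muscle proteins, cartilage matrix, lens crystallins and photoreceptors were reduced, together with fkbp5 and klf9, which are induced by cortisol in many vertebrate tissues. The gene that rose most among named genes was polr2a, which encodes the largest subunit of RNA polymerase II. In all, 341 probe sets (271 named genes) were lower and 256 (159 named genes) were higher in the mutant among 10851 tested, while 53 and 89 of them had no single gene name. The balance turned without mutant array 1 (1179 higher and 866 lower) and at an unadjusted p under 0.05 (1272 higher and 965 lower). It leaned further to lower without the variance trend (137 lower and 27 higher) and with the wild-type SD taken as 2 times the mutant SD (44 lower and 3 higher). The median log2 difference was -0.64 for the lower and +0.43 for the higher probe sets. All 3 mutant arrays lay at least 2-fold below the wild-type array at 62 probe sets and at least 2-fold above it at 2, and all 64 passed the test. Of 89 called genes with more than 1 tested probe set, 75 had all of them on the same side of 0 and 1, sox11b, was called in both directions.

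The 12 largest falls among named genes ranged from -2.97 to -1.70 on the log2 scale. The gene col10a1a, for a collagen of hypertrophic cartilage, read 269 in the wild type and between 18.7 and 21.7 in the 3 mutant arrays, 7.83-fold lower (SE 0.157 on the log2 scale, adjusted p = 4.71e-06). The uncharacterised gene si:ch211-255g12.6 was 6.36-fold lower (adjusted p = 5.27e-06). The embryonic alpha-globin hbae3 fell from 3948 to 717 ± 23.2, 5.41-fold. The cartilage matrix gene matn1 fell by 2.17 on the log2 scale and the muscle calcium buffer pvalb1 was 4.31-fold lower. The cardiac myosin light chain myl7 was 3.85-fold lower and the fast muscle myosin light chain mylpfa 3.51-fold lower. The embryonic beta-globin hbbe3, the red cell anion exchanger slc4a1a and the red cell carbonic anhydrase cahz were 3.43-fold, 3.38-fold and 3.25-fold lower. Outside these tissues, fkbp5, a co-chaperone of steroid receptors, fell 4.74-fold from 239 to 37.8 ± 5.36 (adjusted p = 3.44e-05), and the transcription factor gene klf9 fell 3.72-fold from 129 to 22.9 ± 1.69 (adjusted p = 1.35e-04). In each of these 12 genes all 3 mutant arrays lay below the wild type, as the rule that picked them required. The calls held when any mutant array was left out and when the wild-type SD was taken as 2 times the mutant SD. All of these fits rest on the same wild-type array, so they cannot show whether that array was typical. Globins, parvalbumins, actins and myosin light chains come in families of similar sequence, and part of a signal may be shared between members.

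**Figure D1:**
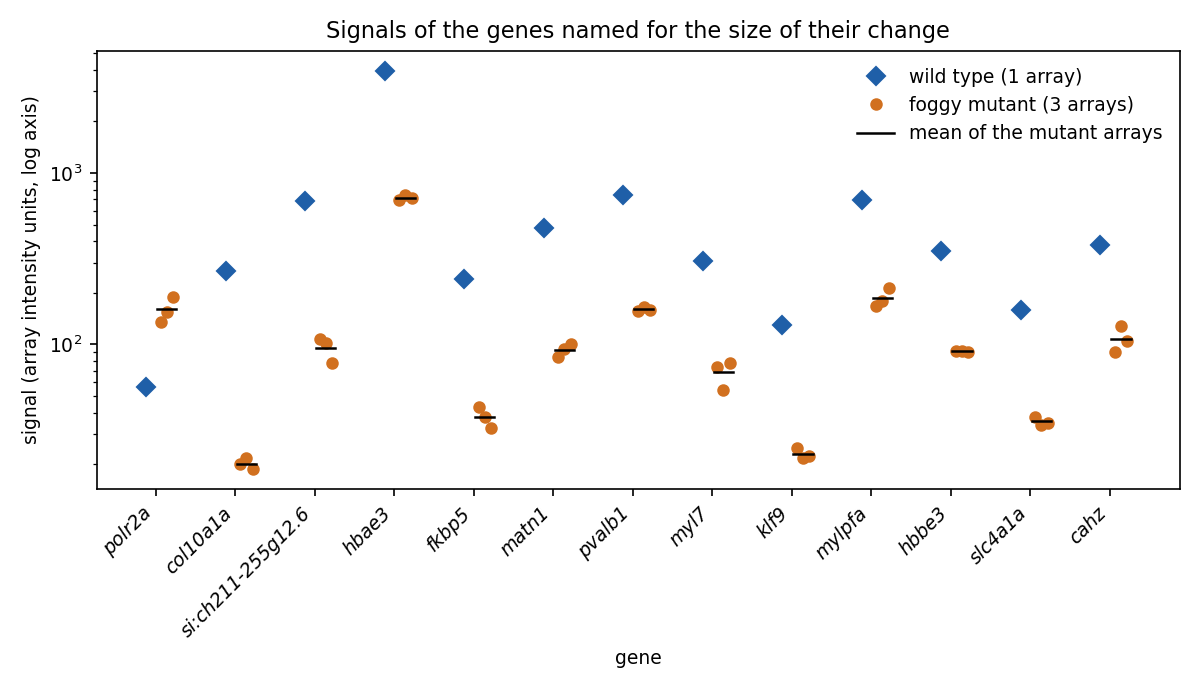
Signal (array intensity units, log axis) of the 13 genes named for the size of their change, with the wild-type array as a diamond, the 3 mutant arrays as circles and their mean as a line. By the rule that picked these genes, polr2a lay above the wild type in all 3 mutant arrays and the 12 other genes lay below it in all 3.

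The gene polr2a was the only named gene to rise at least 2-fold in all 3 mutant arrays. Of its 3 probe sets the middle one in signal read 56.1 in the wild type and 160 ± 26.8 (SD, n = 3) in the mutants, a log2 difference of +1.27 (SE 0.158, adjusted p = 0.00122). The brightest read 158 in the wild type and 366, 340 and 320 in the mutant arrays, a difference of +1.03 (SE 0.0937, adjusted p = 1.86e-04). The remaining one was faint, between 27.4 and 30.5 in all 4 arrays, and differed by 0.07 (adjusted p = 0.873). With the wild-type SD taken as 2 times the mutant SD, the brightest passed (adjusted p = 0.0310) and the middle one did not (adjusted p = 0.127). The other probe set at least 2-fold higher in every mutant array has no gene name here.

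Transcription elongation factors, the class to which Spt5 belongs, shifted upward as a list with the preset correlation (median +0.18, camera adjusted p = 0.00603), and adjusted p = 0.302 with an estimated correlation. Of 23 measured members 3 rose, 0 fell and 20 did not pass, and 3 rose when adjusted over the list alone. The P-TEFb inhibitor hexim1 read 333 in the wild type and 502 ± 25.9 (SD, n = 3) in the mutants, 1.48-fold higher (adjusted p = 0.00284). The Paf1 complex gene ctr9 was 1.37-fold higher (adjusted p = 0.0239) and the P-TEFb cyclin ccnt2b 1.29-fold higher (adjusted p = 0.0244). Of the 23 members 18 lay above 0. None of the 3 single-gene calls held without the variance trend or with the doubled wild-type SD, and those of ctr9 and ccnt2b were also lost without a filter on dim probe sets (adjusted p = 0.0501 and 0.0538). Of 8 RNA polymerase II subunits only polr2a rose, over all probe sets and adjusted over the list alone, and 7 did not pass. The next were polr2f (+0.22, past the threshold without mutant array 1 at adjusted p = 0.0336), polr2j (+0.13) and polr2l (+0.12), and the list had a median of +0.09 and an adjusted p of 0.0602, with 0.0331 without mutant array 1 and 0.0326 without mutant array 2. Of 45 splicing factors, sf3b1 rose (1.23-fold, adjusted p = 0.0230, lost without mutant array 3 at 0.0855, without the variance trend and with the doubled wild-type SD), also adjusted over the list alone, and 44 did not pass. The splicing list had a median of +0.06 and an adjusted p of 0.0212, with an adjusted p of 0.302 with an estimated correlation. That call was lost without mutant array 2 or 3 (adjusted p = 0.0535 and 0.0673), without the variance trend (0.0679) and under cyclic loess (0.0653).

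The skeletal muscle, heart muscle and red blood cell lists each held genes that fell and 0 that rose past the adjusted p over all probe sets. Of 37 skeletal muscle genes 20 fell, 0 rose and 17 did not pass, and 26 fell and 1 rose when adjusted over the list alone. Beside pvalb1 and mylpfa, the parvalbumin pvalb2 went from 1034 to 314 ± 28.6 (SD, n = 3), 3.18-fold, and the myosin light chain mylz3 was 2.70-fold lower. The list's median difference was -0.58 (camera adjusted p = 1.58e-22, and adjusted p = 0.293 with an estimated correlation). Of 9 heart muscle genes 4 fell and 5 did not pass, and 6 fell adjusted over the list alone. They were myl7, the myosin heavy chain myh7 (2.43-fold lower), the light chain cmlc1 (2.32-fold lower) and the actin actc1a (1.33-fold lower), which the skeletal list also holds. The heart list had a median of -0.42 (adjusted p = 2.57e-06, and adjusted p = 0.293 with an estimated correlation). Of 17 red blood cell genes 6 fell and 11 did not pass, while 9 fell and 1 rose adjusted over the list alone. The beta-globin hbbe2 was 3.08-fold lower, beside hbae3, hbbe3 and slc4a1a. The red cell list had a median of -0.26 (adjusted p = 5.17e-09, and adjusted p = 0.293 with an estimated correlation). Its single-array medians were -0.55, -0.21 and -0.19. Among 17 white blood cell genes only lyz, which encodes lysozyme, fell (2.61-fold, adjusted p = 2.40e-05), also adjusted over the list alone, and 16 did not pass (list adjusted p = 0.566).

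In the cartilage, pigment cell, lens and retina lists some genes fell and 0 rose over all probe sets. Of 44 cartilage and mesenchyme genes 7 fell and 37 did not pass, 19 lay above 0, and 8 fell adjusted over the list alone. All 7 encode matrix proteins of which 6 are collagens, among them col2a1a (1.53-fold lower) and col9a2 (1.52-fold lower). The list's median was -0.05 and its mean -0.21, with the mean further from 0 than the median (adjusted p = 0.0169, and adjusted p = 0.302 with an estimated correlation), and the call was lost without the variance trend. Of 11 pigment cell genes 5 fell and 6 did not pass, with 6 adjusted over the list alone. The pteridine enzyme gch2 went from 1143 to 477 ± 7.17 (SD, n = 3), 2.35-fold. The melanin enzyme dct was 1.70-fold lower, the purine enzyme impdh1b 1.69-fold while the melanosome gene pmelb fell by 0.58 on the log2 scale. The pigment list had a median of -0.36 (adjusted p = 3.73e-05, and adjusted p = 0.398 with an estimated correlation). Of 7 lens genes 5 fell and 2 did not pass, over all probe sets and adjusted over the list alone. They included the crystallins crygmxl2 (1.92-fold lower), crybb1 (1.89-fold) and cryba4 (1.44-fold) and the filament gene bfsp2 (log2 difference -1.26). The lens list had a median of -0.68 (adjusted p = 7.20e-07, and adjusted p = 0.302 with an estimated correlation). Of 20 retina and photoreceptor genes 9 fell, 0 rose and 11 did not pass, and 10 fell and 1 rose adjusted over the list alone. The cone transducin subunit gngt2b was 3.10-fold lower, the ultraviolet opsin opn1sw1 2.84-fold, the retinal-binding gene rlbp1a 1.84-fold and rbp4l 1.82-fold. The retina list had a median of -0.44 (adjusted p = 2.25e-06, and adjusted p = 0.293 with an estimated correlation). With the doubled wild-type SD, the calls that held were 10 of 20 in skeletal muscle, 1 of 4 in heart, 5 of 6 in red cells, 2 of 7 in cartilage, 1 of 5 in pigment cells, 1 of 5 in lens and 2 of 9 in retina. Without the variance trend these numbers were 16, 3, 6, 3, 2, 4 and 9, and without a filter on dim probe sets 18, 4, 6, 6, 3, 5 and 9.

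**Figure D2:**
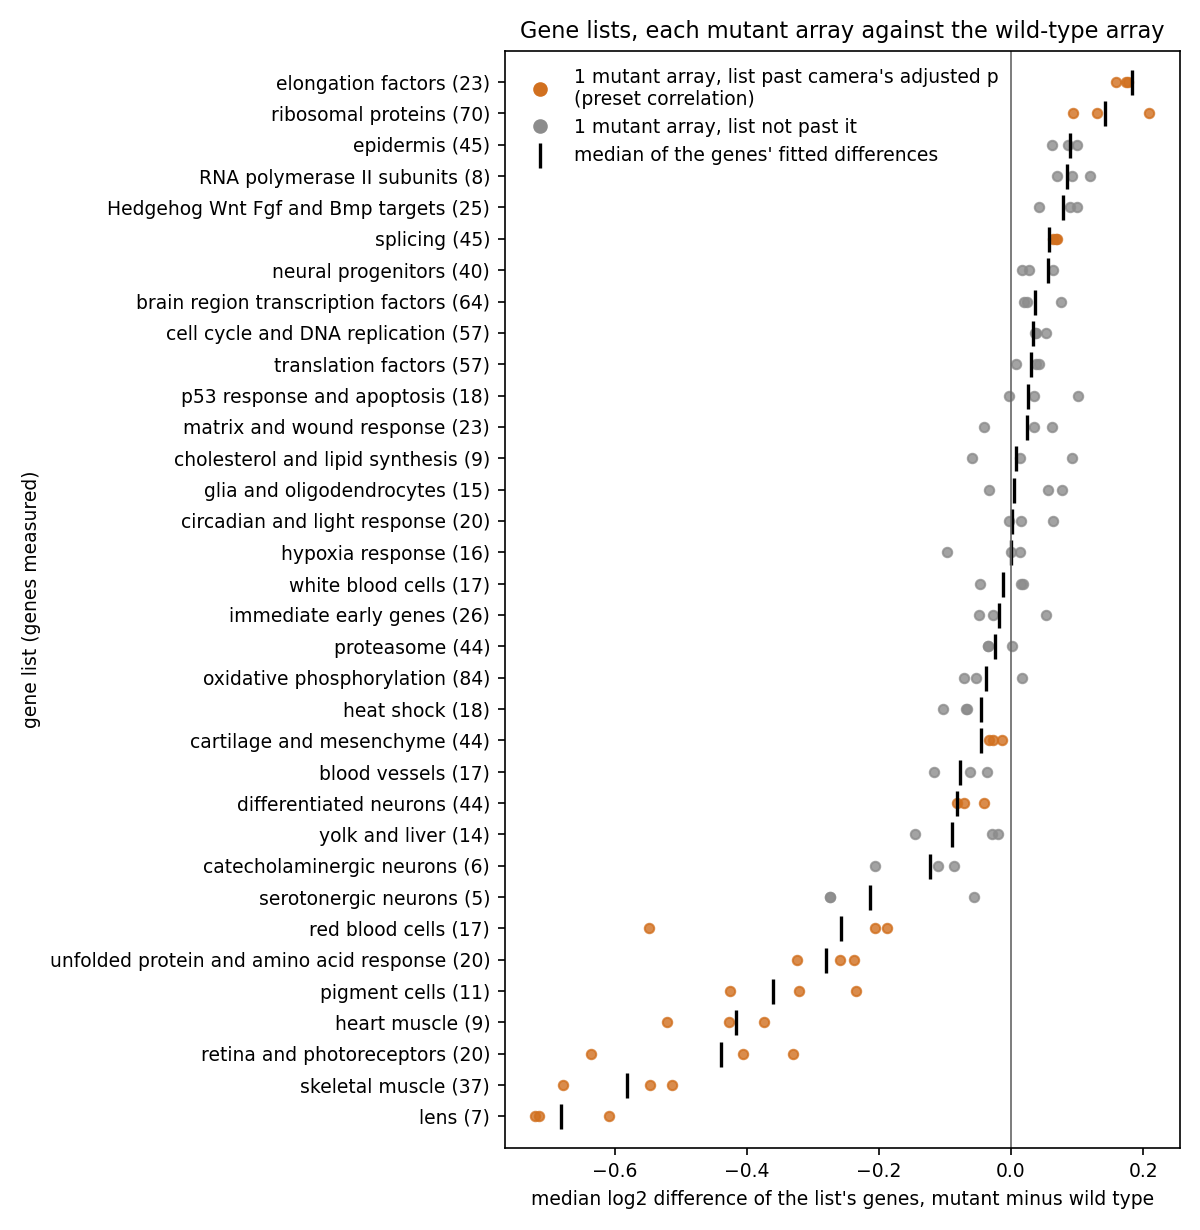
Median log2 difference (mutant minus wild type) of the 34 gene lists, for each of the 3 mutant arrays (circles, coloured where the list passed camera's adjusted p with the preset correlation) and over the fitted differences (bars). The lens, skeletal muscle, retina and heart lists lay lowest, at medians of -0.68, -0.58, -0.44 and -0.42, and the elongation factor list lay highest at 0.18.

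Of 20 genes in the unfolded protein and amino acid response list 8 fell, 0 rose and 12 did not pass, 7 lay above 0, and 12 fell and 1 rose adjusted over the list alone. The calreticulins calr3b and calr were 1.88-fold (adjusted p = 5.78e-04) and 1.43-fold lower, and the chaperones hsp90b1 and hspa5 1.54-fold and 1.47-fold lower. The list's median was -0.28 (adjusted p = 2.05e-04, and adjusted p = 0.302 with an estimated correlation), and 0 of the 8 calls held with the doubled wild-type SD, 2 without the variance trend and 5 without a filter. In the heat shock list the collagen chaperone serpinh1b fell 1.74-fold (adjusted p = 0.00101) and hsp90ab1 rose 1.19-fold (adjusted p = 0.0391), while 16 of 18 did not pass (list adjusted p = 0.124). Neither call held without the variance trend or with the doubled wild-type SD. The hsp90ab1 call was also lost without mutant array 2 or 3 (adjusted p = 0.130 and 0.220), without a filter on dim probe sets (0.0806), under cyclic loess (0.0530) and under quantile normalization (0.142), where its difference went from +0.25 to +0.10. Adjusted over the list alone, 4 fell and 1 rose.

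In the lists of neurons and progenitors genes moved both ways. Of 44 genes of differentiated neurons 9 fell, 2 rose and 33 did not pass, with 13 falls and 6 rises adjusted over the list alone. The calcium-binding calb2a fell 2.07-fold, from 492 to 229 ± 11.7 (SD, n = 3, adjusted p = 1.28e-04). The acetylcholine transporter slc18a3a was 1.63-fold lower, the axon guidance gene islr2 1.51-fold and the motor and sensory neuron factor isl1a 1.43-fold. The 2 rises, named after their values were seen, were slc32a1 (1.34-fold) and elavl4 (1.28-fold), both lost without the variance trend (adjusted p = 0.139 and 0.188). Of the 11 calls 3 held without the variance trend, 8 without a filter and 2 with the doubled wild-type SD. Those of calb2a and islr2 held in both, that of isl1a was lost in both (adjusted p = 0.0740 and 0.115), and that of slc18a3a was lost with the doubled SD (adjusted p = 0.406). The neuron list had a median of -0.08 (adjusted p = 0.0104, and adjusted p = 0.302 with an estimated correlation). Of 40 neural progenitor genes 3 rose, 3 fell and 34 did not pass, and 4 rose and 4 fell adjusted over the list alone. The progenitor genes msi2b and pax6b were 1.64-fold and 1.56-fold lower, and neurod4 and sox11b were 1.29-fold and 1.19-fold higher (list adjusted p = 0.843). The sox11b call was lost without mutant array 2 or 3 (adjusted p = 0.0938 and 0.161) and under cyclic loess (0.0638), and of the other probe sets of sox11b, 1 was lower (-0.89, adjusted p = 3.78e-04) and 1 did not pass (+0.05). Of the 6 progenitor calls 3 held without mutant array 2, 3 without mutant array 3, 2 without a filter, and 0 without the variance trend or with the doubled wild-type SD. Among 57 cell cycle and DNA replication genes 0 passed limma's test, over all probe sets or adjusted over the list alone. The smallest p-values there were those of rpa1 (+0.29, adjusted p = 0.0744), rrm1 (-0.31, adjusted p = 0.0808), gins3 (+0.33) and ncapg (+0.20), all of which passed without mutant array 1 (adjusted p = 9.55e-04, 2.50e-04, 0.0455 and 0.00997), and rpa1 and rrm1 also without mutant array 2 (0.0390 and 0.0180). That list's adjusted p was 0.481.

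Glial and regional genes moved singly. Of 15 glia and oligodendrocyte genes 3 fell, 1 rose and 11 did not pass, with 3 falls and 2 rises adjusted over the list alone (list adjusted p = 0.649, with a median of +0.01, a mean of -0.04 and a test direction of down). The glutamine synthetase glula was 1.69-fold lower and the gap junction gene gja1b 1.57-fold lower. The radial glia gene fabp7a was 1.18-fold lower (adjusted p = 0.0496) and lost its call without mutant array 2 or 3 (adjusted p = 0.130 and 0.275) or under median centring (0.0557). The rise was that of id4, 1.24-fold, lost without mutant array 3 (adjusted p = 0.0712). Of 64 brain region transcription factors 2 rose, 2 fell and 60 did not pass, with 2 rises and 4 falls adjusted over the list alone (list adjusted p = 0.803). The forebrain gene dlx2a was 1.42-fold higher (adjusted p = 0.00451), pbx4 1.25-fold higher, the telencephalic gene eomesa 1.52-fold lower and meis1b 1.26-fold lower. The eomesa call was lost without mutant array 2 (adjusted p = 0.0605), and that of pbx4 without mutant array 2 or 3 (adjusted p = 0.0709 and 0.0728). Of 6 catecholaminergic neuron genes tfap2a fell (1.26-fold, adjusted p = 0.0163) and 5 did not pass, with 1 fall and 1 rise adjusted over the list alone (list adjusted p = 0.481). The hypothalamic gene otpb differed by +0.24 (adjusted p = 0.0585, and 1.90e-04 without mutant array 1), ret by -0.45 and arnt2 by -0.18. Of 5 serotonergic neuron genes 0 passed, over all probe sets or adjusted over the list alone (list adjusted p = 0.224). Beside tph2, gata3 differed by -0.30 (past the threshold without mutant array 1, adjusted p = 0.0467), tph1a by -0.21 and mao by +0.11. Of the 9 calls in these glial and regional lists 1 held without the variance trend, 6 without a filter and 0 with the doubled wild-type SD. The median of the 5 serotonergic genes, -0.21, lay at percentile 3.34 of random lists. With few members measured, th and slc6a3 too dim to test and tph2 not passing, a shift of these neurons was not readable here.

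Of 70 measured ribosomal protein transcripts 69 had a difference above 0. Their median of +0.14 lay at percentile 94.8 of random lists matched on mean expression, and the single-array medians (+0.21, +0.09 and +0.13) were near the offsets of the hybridisation spikes of these arrays (+0.21, +0.14 and +0.16). Of the 70 only rpl35 rose (1.24-fold, adjusted p = 0.0189), also adjusted over the list alone, and 69 did not pass. The rpl35 call was lost without mutant array 3 (adjusted p = 0.130). Camera's adjusted p was 1.20e-10 with the preset correlation, with an adjusted p of 0.631 with an estimated correlation. Under quantile normalization the median was +0.02 and the call was lost (adjusted p = 0.0651). Nuclear oxidative phosphorylation genes did not pass as a list (median -0.04, adjusted p = 0.0997), with 3 falls, 1 rise and 80 not passing of 84, and 2 falls adjusted over the list alone. They passed under cyclic loess (adjusted p = 0.0162). The falls included ndufa4b (1.64-fold) and cox6b1 (1.39-fold). Of the 4 calls 2 held without mutant array 2 and 2 without mutant array 3. Of 57 translation factors eif3s10 rose 1.21-fold and eif4a1a fell 1.21-fold, with 1 fall adjusted over the list alone (list adjusted p = 0.795). Of 44 proteasome genes psma5 fell by 0.27 on the log2 scale, with 0 calls adjusted over the list alone (list adjusted p = 0.343). These 3 calls were all lost without mutant array 2 (adjusted p = 0.0907, 0.0676 and 0.0964) or 3 (0.0661, 0.108 and 0.103). Of 18 genes of the p53 response and apoptosis, gadd45ga rose 1.43-fold (adjusted p = 0.0205), also adjusted over the list alone, and 17 did not pass (list adjusted p = 0.788). None of the 9 single-gene calls in these lists held without the variance trend or with the doubled wild-type SD, and 5 held without a filter.

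The wild-type array differed more from the mutant arrays than these did from one another. Pearson's r across probe sets, which are not independent, was 0.980 to 0.982 between wild type and mutants and 0.991 to 0.994 between mutants, and the SD of the log2 differences was 0.274 to 0.288 and 0.158 to 0.196. Against only the other 2 mutant arrays, mutant array 1 gave 514 calls and 1897 probe sets at an unadjusted p under 0.05. The wild-type array gave 2045 calls against the same 2 arrays. Its 597 calls and 2237 such probe sets came from a fit against 3 arrays and are no like measure. Mutant arrays 2 and 3, each against the other 2 mutant arrays, gave 0 and 1 calls and 321 and 268 such probe sets. The wild type against those same pairs of arrays made more calls. The rule of size gave 1, 0 and 0 probe sets in the 3 fits of a mutant array against the other 2. With a mutant array set against all other 3, limma made 0 calls (510, 116 and 110 at an unadjusted p under 0.05), but there the wild-type array lies within the group of 3 and widens its spread, so this is no measure of chance. In simulated arrays without any change, a wild-type SD of 2 times the mutant SD gave a median of 496.5 calls with 25 probe sets beyond 2-fold, and one of 3 times gave 3119 and 173.5. Without mutant array 1 the calls rose from 597 to 2045. With the wild-type SD taken as 2 times the mutant SD, a fit added after the data were seen, 47 probe sets passed (44 lower and 3 higher). The hybridisation spikes of the mutant arrays were 0.21, 0.14 and 0.16 log2 units above those of the wild-type array, and the 3' to 5' ratio of the GAPDH control was 1.78 in the wild type and 1.77, 1.93 and 1.92 in the mutants.

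**Figure D3:**
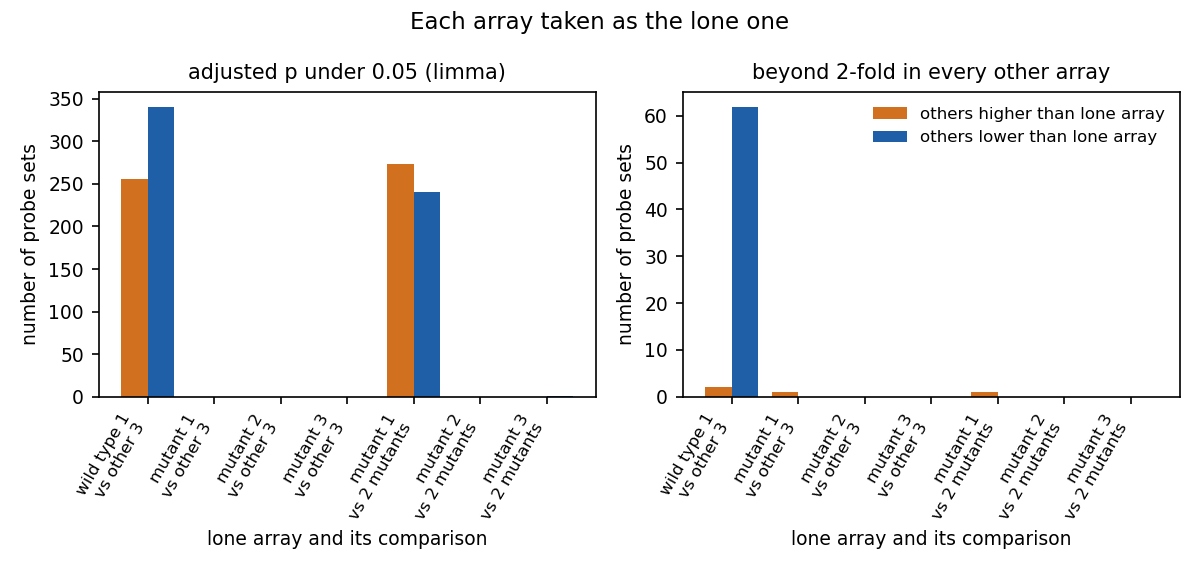
Number of probe sets past limma's adjusted p (left) and beyond 2-fold in every other array (right), with each array in turn as the lone one, against the other 3 arrays or, for the mutants, against the other 2 mutant arrays. In the fits of a mutant array against the other 3, the wild-type array is in the group of 3 and widens its spread. The wild-type array stands out on the right with 62 probe sets lower and 2 higher in all mutant arrays. On the left, the 514 calls of mutant array 1 come from a fit against 2 arrays and the 597 of the wild type from a fit against 3. These 2 bars are therefore not directly comparable. The like fit of the wild type against those 2 arrays, not drawn here, made more calls.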

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

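Among the processing alternatives, only the fit with a larger wild-type SD was chosen after the data were seen. The 13 genes named for the size of their change kept their direction and passed under each other alternative in which they were measured, although the filter at the 50th percentile left out col10a1a, fkbp5, klf9 and slc4a1a. Of 1818 values of named genes under the alternatives, 1618 stayed on their side of the threshold, 163 lost it, 37 gained it and 0 changed sign. Of 474 gene list values, 451 stayed, 18 lost the call (12 of these with an estimated correlation), 5 gained it, and 16 of lists that were not called changed sign. Without a filter on dim probe sets 380 probe sets passed (129 higher) and the ratio of wild-type-to-mutant over mutant-to-mutant SD went from 1.53 to 1.297. Without the variance trend, 164 passed (27 higher, 137 lower), and with the wild-type SD taken as 2 times the mutant SD, 47 passed (3 higher, 44 lower). With an estimated correlation in camera, 0 lists were called, 0 higher and 0 lower, against 12, 3 and 9. Even the skeletal muscle list went from a camera adjusted p of 1.58e-22 to 0.293. With 2 residual degrees of freedom that test had little power, so the lost calls decide nothing about the lists. A pseudocount at the 5th percentile gave 5 probe sets beyond 2-fold higher and a ratio of 1.47, one at the 40th percentile gave 0 and 1.62, and a filter at the 50th percentile gave 1 and 1.71. Leaving out 1 mutant array gave 557 to 2045 calls, 213 to 1179 higher and 344 to 866 lower, with the highest of each without mutant array 1, a ratio of 1.43 to 1.74, and a supt5h difference of 0.233 to 0.269, which passed without mutant array 1 (adjusted p = 0.0447). Under cyclic loess all 341 lower probe sets were still called lower and 204 of the 256 higher ones still higher, and 66.2% of the calls were lower against 57.1%. The RNA polymerase II subunit list passed without a filter (adjusted p = 0.0355), without mutant array 1 (0.0331) or 2 (0.0326) and with the larger wild-type SD (0.0411). That list holds polr2a (+1.03 in the main fit), and its 7 other members had a median of +0.05 there, so these passes do not show a shift of the other subunits. For the shifts between settings the cause was not tested. No paired analysis was possible because the groups share only replicate number 1. Signals near the pseudocount of 16.252 units limit what can be read, and th and slc6a3 lie below it.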

Other observations

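The tests of epidermis against muscle, of muscle regulators against the fixed muscle list, of polr2a against the other subunits and of a single faulty probe set were chosen only after the result was seen, as were the 4 added gene lists. Stress and signalling genes moved singly in the mutant. Of 26 immediate early genes 4 rose, 2 fell and 20 did not pass, over all probe sets and adjusted over the list alone, and the list did not pass (adjusted p = 0.649, with a median of -0.02, a mean of +0.05 and a test direction of up). Of the 6 calls 5 held without mutant array 2 or 3. The stress factor gene atf3 was 1.86-fold higher (adjusted p = 0.00499), and ier5l 1.54-fold higher, klf2b rose by 0.68 on the log2 scale, and cebpd 1.53-fold lower. Of 16 genes of the hypoxia response igfbp1a rose 1.74-fold (adjusted p = 3.57e-04) and pfkfb4b fell 1.59-fold, over all probe sets and adjusted over the list alone, while 14 did not pass, among them ndrg1b (+0.29) and vegfaa (+0.46), both of which passed without mutant array 1 at 0.0113 and 0.0289 (list adjusted p = 0.993, with a median of 6.31e-04, a mean of +0.02 and a test direction of down). Of 25 targets of Hedgehog, Wnt, Fgf and Bmp signals only id4 rose, also adjusted over the list alone, a call lost without mutant array 3 (adjusted p = 0.0712), and etv5b (+0.33), hhip (+0.29) and id3 (+0.21) did not pass, with etv5b and id3 past the threshold without mutant array 1 (0.0170 and 0.0126) (list adjusted p = 0.270). Of 23 genes of the matrix and wound response s100a10b rose 1.18-fold, a call lost without mutant array 2 (adjusted p = 0.118) or 3 (0.150) and under cyclic loess (0.0705), with 0 calls adjusted over the list alone (list adjusted p = 0.823, with a median of +0.02, a mean of -0.02 and a test direction of down). Of the 10 calls in these lists 3 held without the variance trend, 7 without a filter on dim probe sets and 0 with the doubled wild-type SD. Among 9 cholesterol and lipid synthesis genes 0 passed limma's test over all probe sets or adjusted over the list alone (list adjusted p = 0.934).

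Skin genes went in both directions. Of 45 epidermis genes 7 rose, 6 fell and 32 did not pass, with 12 rises and 7 falls adjusted over the list alone (median +0.09, list adjusted p = 0.234). The keratin krt97 was 1.67-fold higher and the annexin anxa1c 1.61-fold higher, while anxa1b was 1.69-fold lower and zgc:136930 fell by 0.68 on the log2 scale. Of the 13 epidermis calls 9 held without mutant array 2, 9 without mutant array 3, 6 without the variance trend, 9 without a filter and 2 with the doubled wild-type SD. Of 17 blood vessel genes esm1 rose 1.73-fold and the flow-responsive klf2a fell 1.65-fold, over all probe sets and adjusted over the list alone, and 15 did not pass (list adjusted p = 0.649). Both calls were lost without a filter on dim probe sets (adjusted p = 0.0617 and 0.0608) and with the doubled wild-type SD (0.730 and 0.739), and that of klf2a without the variance trend (0.0862). The blood stem cell factor tal1 differed by +0.40 (adjusted p = 0.149, and 0.0105 without mutant array 1), beside the fall of the globins. Of 14 yolk and liver genes rbp4 fell 1.48-fold and ctsla rose 1.36-fold, with 3 falls and 1 rise adjusted over the list alone (list adjusted p = 0.337), and neither call held without the variance trend or with the doubled wild-type SD. Of 13 muscle regulators, an added list, 0 passed limma's test, over all probe sets or adjusted over the list alone (median -0.04, list adjusted p = 0.610), and of 20 contractile genes 18 fell, with 19 falls and 1 rise adjusted over the list alone (median -1.19), in an added list that was written after such falls were seen and so is no separate evidence of a fall. Named after their values were seen, the basal transcription factor gene gtf2a1 rose by 0.68 on the log2 scale (adjusted p = 0.00274, lost without the variance trend at 0.0740 and with the doubled wild-type SD at 0.226), and of 4 probe sets of brd2a 1 rose 1.85-fold while the other 3 did not pass.

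The fall of muscle, blood, cartilage, lens and photoreceptor genes may reflect what the samples held as well as what the mutation does. Less non-brain tissue of every kind would lower skin genes with muscle genes, but the 45 epidermis genes had a mean difference of +0.02, which is 0.730 above that of skeletal muscle (95% bootstrap interval over genes 0.507 to 0.954). Cyclic loess, which removes intensity-dependent scaling, left 100% of the 341 lower calls and 204 of the 256 higher calls in place. It moved the median difference of all tested probe sets from +0.024 to -9.0e-04, so lower calls were less likely to be lost than higher ones. Less skeletal muscle should lower its regulators with its other genes. The 13 regulators lay 0.803 above the 31 other genes of the fixed skeletal muscle list (0.558 to 1.06). The 6 at or above the array's median signal lay 0.693 above (0.451 to 0.936). Faint regulators can show little of a fall, and some regulators are also expressed in brain, so these gaps cannot exclude less skeletal muscle. The gap of 1.07 (0.775 to 1.35) to contractile genes is not used, as these were chosen after their falls were seen. An earlier stage is a candidate explanation that stays open, since progenitor and cell cycle genes lay 0.152 above differentiated neuron genes (0.0570 to 0.254). The gap came from the neuron genes (mean -0.126). The progenitor and cell cycle genes did not rise as a set, as their mean of +0.026 was near the median of all tested probe sets (+0.024). The mutation itself and a dissection that differed for each tissue separately were not tested and stay open, some list members are shared between lists (2 of 37 in skeletal muscle, 4 of 44 in cartilage), and the intervals cover the spread between genes, not between embryos.

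The fall of fkbp5 and klf9 may reflect lower glucocorticoid signalling in the mutant samples. Among 23 other cortisol-induced genes 3 fell (glula, cebpd and sgk1) and 0 rose, with 4 falls and 1 rise (foxo3a, +0.39) adjusted over the list alone and 8 members above 0, the median was -0.17, and it lay at percentile 0.04 of random lists (camera adjusted p = 0.00786, and adjusted p = 0.168 with an estimated correlation). Of these 23 genes, 12 belong to other lists too, and all 3 calls were lost with the doubled wild-type SD and without the variance trend (glula 0.0585, cebpd 0.0716 and sgk1 0.104). The cortisol list was written after the first results were seen, and glula and cebpd are also named falls of lists fixed before. Its percentile and its camera p, adjusted over the 4 added lists alone, are therefore not independent evidence of lower glucocorticoid signalling. Another time of day at collection cannot be told apart, because 2 of 20 circadian genes passed, in opposite directions (nr1d2a 1.80-fold lower and bhlhe40 1.31-fold higher, the latter lost without mutant array 2 or 3 at adjusted p = 0.0577 and 0.0566, and both lost without a filter at 0.0501 and 0.0535 and with the doubled wild-type SD at 0.650 and 0.779), and no collection time is given in the sources used here. The circadian list had a median of 0.00206, a mean of -0.03, a test direction of up and an adjusted p of 0.934, and an effect of the mutation on these genes stays open as untested.

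The rise of polr2a in mutants of an elongation factor is a candidate for follow-up. A fault of 1 probe set is argued against by 2 probe sets of the gene that rose, though the faint one did not. A rise of all RNA polymerase II subunit transcripts by as much as polr2a is argued against by the 7 other subunits, which lay between -0.02 and +0.22, with a median 0.984 below the brightest polr2a probe set. A smaller common rise cannot be told apart, as the planned test decided nothing. The median of the 7 other subunits, +0.05, lay at percentile 65.5 of random lists, between that test's bounds of 50 and 95. The pass of polr2f without mutant array 1 (adjusted p = 0.0336) is weak evidence, as said above. Of 44 general transcription factor genes 1 rose, also adjusted over the list alone. Their median of +0.05 lay at percentile 86.6 of random lists (camera adjusted p = 0.0447, and adjusted p = 0.168 with an estimated correlation). That list was written after the first results were seen. Its camera p was adjusted over the added lists alone, so it does not decide the question either. Whether the mutation raises polr2a itself, or a longer or differently processed transcript that these probe sets read, was not tested.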
